A study of Mus musculus with 18 samples.

How the data were processed

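Kidneys of wild-type (WT) mice and of mice lacking Ecm1 (KO) were sampled at 1, 2 and 4 weeks of age, with 3 RNA sequencing libraries in each of 6 groups and 18 libraries in all. Per the labels' protocols, total RNA was extracted from the tissue with Trizol, mRNA was captured on beads, fragmented and copied into cDNA, and the libraries were read on an Illumina NovaSeq X Plus. Whether the libraries kept the strand is not given in the sources used here, so reads of a gene could not be told from those of an overlapping or antisense partner. The labels give tissue and genotype. They give neither strain nor sex, and they do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may in part be technical.

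The deposited table holds 22063 genes, each with an Ensembl identifier and a symbol. For each library the authors deposited an estimated count and an FPKM value per gene (fragments per kilobase and per library total), per the file headers. Between 6.86% and 8.44% of the count values of a library were not whole, so the deposited counts were taken to be fractional (expected) counts and rounded to whole numbers before any count test. The submitters' processing notes name fastp, Bowtie2, HISAT2 version 2.1.0, StringTie version 1.3.1 and RSEM, with no order or role. The genome build and the annotation are not given in the sources used here. Positions printed in the text come from the GENCODE M21 annotation of GRCm38, in which 21973 of the 22063 identifiers were found and 90 were not. A symbol was missing for 30 genes. Where a symbol had several identifiers, a gene list took the identifier with the larger total.

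Total counts per library ran from 14930565 to 21427764. Values per library are given as CPM computed from the deposited counts with TMM scaling, and log2 values were computed from the deposited counts with a prior count of 2. The principal components and the gene list tests used these log2 CPM values. All group values are means ± SD over 3 libraries, and fold changes are given on the log2 scale ± SE. Counting intervals are exact Poisson intervals at the 95% level and cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

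Differences were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test with TMM scaling and the default expression filter by group. The filter kept 14774 genes. All 18 libraries were fitted in 1 model with 6 group means, which left 12 residual degrees of freedom, because 3 libraries against 3 give few degrees of freedom on their own. The contrasts were KO against WT at each age, their average over the 3 ages, each step in age within each genotype, and the interaction of genotype with age. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The verbs rose and fell are used for called genes.

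Gene lists, 38 in number, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They hold markers of kidney cell types, matrix genes, genes of metabolism and stress, genes with a known sex bias in mouse kidney, and markers of other tissues that a kidney sample can carry. Each list was tested against the other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. For each list the number of called members is given over all genes tested and adjusted over the list alone. A list of hepatocyte markers was added after the data were seen.

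The genes named in the text follow a fixed rule. For KO against WT at 1 age it takes Ecm1, then the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM in the higher group and no overlap between KO and WT libraries, leaving out provisional names. Where fewer than 5 genes pass, the 5 with the smallest unadjusted p are given as values. Up to 4 members with the smallest p are taken from each list. The average over ages takes up to 8 rises and 8 falls with 1 sign at the 3 ages, the interaction takes 6 genes, and each step in age takes up to 5 rises and 5 falls. A subset of the genes so chosen is named. A gene outside the rule is said to be chosen after its values were seen.

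The replicate numbers of the labels were checked for pairing. At 2 weeks the deviations of WT and KO libraries from their group means were correlated across genes. Same-numbered libraries had correlations of 0.68, 0.31 and 0.46 for numbers 1, 2 and 3. The other combinations ran from -0.56 to 0.35. The highest of these was WT replicate 2 with KO replicate 3, above WT replicate 2 with its own number. The numbers were taken to pair the libraries at that age, most clearly for number 1, with nothing in the labels to say why. At 1 week the same-number correlations were -0.04, 0.18 and 0.18, and at 4 weeks 0.07, 0.16 and 0.01. There the numbers were not taken to pair the libraries. No 2 libraries of a group were alike within sampling noise, since chi-square per gene over the 18 pairs within groups ran from 7.39 to 76.9.

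The sex of each mouse was read from the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y as a check. The alternatives were the median-of-ratios scaling of DESeq2 within edgeR, DESeq2 1.42.0, no expression filter, a filter of 1 CPM in 3 libraries, limma on log2 of FPKM plus 1 or plus 0.1 over 13164 genes, the replicate number as a block, the 6 libraries of an age alone, sex as a covariate, the removal of blood, adrenal, adipose and immediate-early genes, a minimum log2 fold change of 1, and leaving out each library in turn. On the FPKM scale a fold change understates the change of genes with low values.

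Each test was tried on simulated counts drawn from a negative binomial distribution with the means, dispersions and library sizes of the real data with 200 changed genes, 100 at a log2 fold change of 1 and 100 at 2. For KO against WT, edgeR recovered 75% and 95% of them at 1 week (14583 genes), 67% and 95% at 2 weeks (14589 genes), and 62% and 96% at 4 weeks (14586 genes), with 6.08%, 4.71% and 4.24% false calls. At 4 weeks DESeq2 recovered 68% and 98% with 11.7% false calls, and limma on log2 CPM 62% and 97% with 4.79%. The average over ages gave 93% and 96% (14596 genes) and the interaction 46% and 85% (14587 genes). All 5 changed lists were recovered by camera with either correlation and by fry in the 4-week simulation (14586 genes), with 0 false lists among the 33 unchanged ones. Genes in these simulations varied independently of each other, unlike those of real lists. Each gene had the same mean, apart from the change, and the same dispersion in all groups, and changed genes had a mean of at least 1 CPM. In the real data the spread was unequal, with chi-square per gene at 4 weeks from 8.14 to 16.8 within WT and from 37.6 to 43.9 within KO. The recovery and false-call rates may therefore not carry over to the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.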

Results

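RNA was sequenced from kidney tissue of WT and Ecm1 KO mice at 1, 2 and 4 weeks of age. Ecm1 encodes a secreted glycoprotein of the extracellular matrix. The study's title places its source in the mesangial cells, the pericyte-like cells that hold the capillary loops of the glomerulus together. Mouse kidneys form their last nephrons in the days after birth and mature over the following weeks. The 3 ages span the end of nephron formation, the maturation of the tubules and the start of puberty. Each of the 6 groups had 3 libraries, with total counts between 14930565 and 21427764 per library. The design asks what the kidney transcriptome loses or gains without Ecm1 at each age, and whether that difference changes with age.

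Ecm1 itself (ENSMUSG00000028108) was nearly absent from every KO library. In the GENCODE M21 annotation of GRCm38 the gene lies on the minus strand of chromosome 3, from 95734147 to 95739569, and its transcript Ecm1-201 has 11 exons. Which part of the gene was targeted is not given in the sources used here, and the counts cover the whole gene. The WT level was 41.4 ± 2.70 CPM at 1 week, 48.4 ± 8.53 at 2 weeks and 42.5 ± 13.7 at 4 weeks, against 0.0292 ± 0.0506, 0.0158 ± 0.0273 and 0.0957 ± 0.0375 CPM in KO (SD, n = 3). No KO library held more than 2 Ecm1 counts, whereas WT libraries held from 301 to 1315. The KO level was 0.0775% of WT at 1 week (95% exact Poisson interval 0.00938 to 0.280), 0.0335% at 2 weeks (0.000849 to 0.187) and 0.227% at 4 weeks (0.0618 to 0.581). Each of the 3 differences passed the edgeR quasi-likelihood test, with adjusted p of 2.55e-09, 1.59e-09 and 9.00e-09. No library went against its genotype label.

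**Figure D1:**
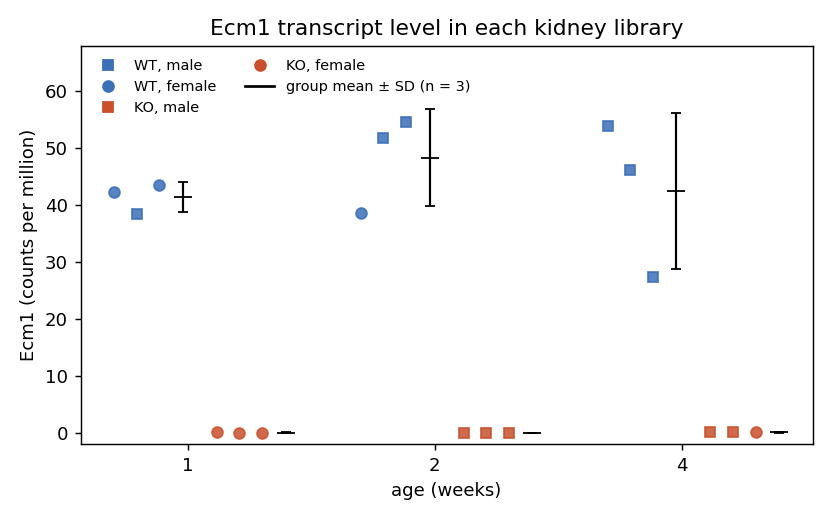
Ecm1 level in CPM (vertical axis) against age in weeks (horizontal axis), 1 point per library, WT in blue and KO in red, squares for males and circles for females as read from Y-linked genes, with the group mean and SD (n = 3) beside the points. WT means lie between 41.4 and 48.4 CPM and every KO library lies near 0.

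Age was the main axis of the data. The first principal component held 64.9% of the variance of log2 CPM and ordered the libraries by age, and the second held 8.50%. At 4 weeks the 3 KO libraries lay between the WT libraries of 4 weeks and the libraries of 2 weeks on the first component. Y-linked genes showed that the mice were of both sexes in an uneven pattern. At 1 week WT had 1 male and 2 females and KO had 3 females. At 2 weeks WT had 2 males and 1 female and KO had 3 males. At 4 weeks WT had 3 males and KO had 2 males and 1 female, which was KO replicate 3. Mitochondrial transcripts took 8.80% to 10.1% of the counts at 1 week and 18.4% to 21.7% at 4 weeks.

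**Figure D2:**
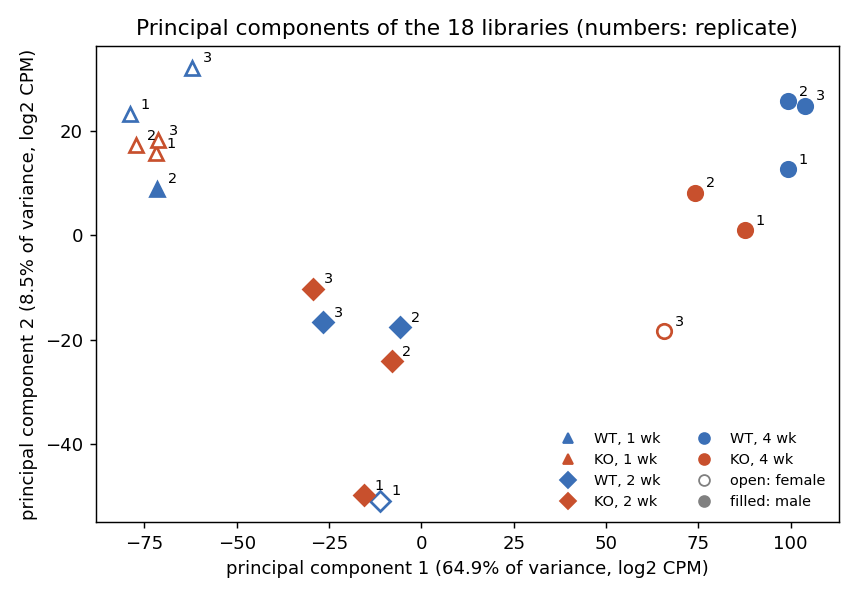
First and second principal components of log2 CPM (axes in component scores, with 64.9% and 8.50% of the variance), 1 point per library, WT in blue and KO in red, with triangles for 1 week, diamonds for 2 weeks and circles for 4 weeks, open for females and filled for males, and the replicate number beside each point. The libraries follow age along the first component, and the KO libraries of 4 weeks lie to the left of the WT libraries of 4 weeks.

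At 1 week Ecm1 was the only gene called between KO and WT kidneys by edgeR. Of the 14774 genes tested, 196 had an unadjusted p under 0.05, where 739 would be expected if no gene differed. DESeq2 called 4 genes (Ecm1, Rbm46 and the Y-linked Uty and Ddx3y), with 217 genes at an unadjusted p under 0.05. Limma on log2(FPKM + 1) called 2. After Ecm1 the smallest p belonged to Rbm46, which encodes an RNA-binding protein of the germ line and lies on chromosome 3, at 2.24 ± 0.636 CPM in WT and 0.253 ± 0.165 in KO (log2 fold change -3.10 ± 0.51, adjusted p = 0.113). S100a16 stood at 58.7 ± 3.41 CPM in WT and 44.3 ± 6.54 in KO, and the neurofilament gene Nefh at 0.988 ± 0.161 and 0.417 ± 0.0563. Itih2 and Vtn, which encode plasma proteins made mainly by the liver, had means of 6.29 ± 9.56 and 3.41 ± 5.38 CPM in WT. Their level there came from WT replicate 3, with 17.3 and 9.63 CPM against at most 0.962 and 0.366 in the other 2 WT libraries.

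The gene lists did not separate the genotypes at 1 week more than other groupings of the same libraries did. Camera with the preset correlation called 7 of 38 lists. The nuclear genes of oxidative phosphorylation had all 34 members at a positive fold change with a median of 0.15 (adjusted p = 1.05e-08, and adjusted p = 0.929 with an estimated correlation), and the call was lost without KO replicate 1 (adjusted p = 0.174). Markers of the loop of Henle and the distal convoluted tubule had a median of 0.17 (adjusted p = 0.00146, and 0.584 with an estimated correlation). Endothelial markers had a median of -0.14 (adjusted p = 0.000167, and 0.584 with an estimated correlation). By edgeR 0 members of each of these lists were called over all genes or adjusted over the list alone. The other lists were collecting duct (median 0.06, adjusted p = 0.0242) and macrophage markers (0.13, 0.0276) above the other genes, and adrenal genes (-3.47, 0.00271) and sex chromosome genes (-9.58, 0.0276) below them. They had adjusted p = 0.584, 0.929, 0.635 and 0.929 with an estimated correlation. The collecting duct call was lost without WT replicate 3 (adjusted p = 0.582), KO replicate 1 (0.0726) or KO replicate 3 (0.139), and the macrophage call without WT replicate 2 (0.209), WT replicate 3 (0.155), KO replicate 1 (0.855) or KO replicate 2 (0.0943). The adrenal genes followed WT replicate 3, in which 5 of the 6 were highest of all 18 libraries, and without it the list turned upward (adjusted p = 0.346). The sex chromosome genes followed the single male, WT replicate 2, without which the list turned upward (adjusted p = 0.979), and their call was also lost without KO replicate 1 (0.0726), KO replicate 2 (0.0943) or KO replicate 3 (0.117). In these lists 3 and 4 members passed adjusted over the list alone. With an estimated correlation 0 lists passed, and by fry 0 lists passed. Each of the other 9 splits of the 6 libraries gave 7 to 15 lists with the preset correlation. Without WT replicate 1 the real split gave 12 lists and without KO replicate 1 it gave 3.

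At 2 weeks Ecm1 was again the only gene called by edgeR, with 249 genes at an unadjusted p under 0.05. DESeq2 called Ecm1 and Serpina1f with 281 genes at an unadjusted p under 0.05. Serpina1f, a member of the serpin family, stood at 12.9 ± 4.28 CPM in WT and 31.3 ± 11.1 in KO (log2 fold change 1.27 ± 0.27, edgeR adjusted p = 1). Mttp, which loads lipid onto apolipoprotein B, stood at 19.6 ± 5.04 and 10.2 ± 1.45 CPM. Mfap4, a protein of elastic fibres, had a log2 fold change of 1.14 ± 0.28 (adjusted p = 1), Rbm46 stood at 1.09 ± 0.183 and 0.224 ± 0.0548 CPM, and Tmem132d at 0.164 ± 0.118 and 0.893 ± 0.266. The count of called genes stayed at 1 with the replicate number as a block.

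Camera with the preset correlation called 13 lists at 2 weeks, 10 with the replicate number as a block, 8 without WT replicate 1, 8 without KO replicate 1 and 7 without KO replicate 2. None, 0 of 38, passed with an estimated correlation (smallest adjusted p = 0.313) or by fry (smallest adjusted p = 0.942). No member of any list was called over all genes, and adjusted over the list alone 8 members passed, 6 of them erythroid genes. Fibrillar matrix genes had a median log2 fold change of 0.18 (adjusted p = 0.000351, and 0.819 with an estimated correlation). KO replicate 3 held the highest level of 21 of the 30 at 2 weeks, and the call was lost without it (adjusted p = 0.290), without WT replicate 1 (0.176) or without WT replicate 2 (0.0507). Podocyte markers had a median of -0.11 (adjusted p = 0.00048, and 0.471 with an estimated correlation), and their call was lost without WT replicate 1 (adjusted p = 0.104). Haemoglobin and erythroid genes had a median of -2.40 (adjusted p = 1.21e-06, and 0.357 with an estimated correlation). Interferon response genes had a median of 0.21 (adjusted p = 1.62e-05, and 0.718 with an estimated correlation). Without WT replicate 1 the interferon list turned downward (adjusted p = 0.980), and without KO replicate 2 it was not called (adjusted p = 0.0737). A list of mouse strain variants, 9 of them tested, had a median of 0.11 (adjusted p = 0.0199, and 0.313 with an estimated correlation), and its call was lost without WT replicate 1 (adjusted p = 0.152), WT replicate 3 (0.109), KO replicate 1 (0.206) or KO replicate 2 (0.116). The erythroid genes stood highest in WT replicate 3, where the haemoglobin gene Hbb-bs (chosen after its values were seen) had 931 CPM against 53.0 to 195 in the other libraries of 2 weeks. The erythroid list nevertheless kept its camera call at the preset correlation in each of the 6 fits without 1 library. Its adjusted p without WT replicate 3 was 0.0296. The replicate number moved far more genes than the genotype at this age. An edgeR test over the 3 numbers with genotype in the model called 3309 genes at 2 weeks, 3 at 1 week and 7 at 4 weeks. One of them was Cirbp, a cold-inducible RNA-binding protein chosen after its values were seen, with 109 and 99.0 CPM in WT and KO replicates 1 and 12.6 to 23.0 CPM in the other 4 libraries.

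At 4 weeks the KO and WT kidneys differed widely. By the list means, podocyte markers stood higher in all 3 KO libraries than in any WT library of that age, and fibrillar matrix and immediate-early genes did so in KO replicates 2 and 3 alone. These lists passed camera with the preset correlation but not with an estimated one (adjusted p = 0.246, 0.402 and 0.402 with an estimated correlation). Of 14774 genes, 477 were called, 223 higher and 254 lower, and 200 of them had an absolute log2 fold change of at least 1. An unadjusted p under 0.05 was found for 2526 genes. Limma on log2(FPKM + 1) gave 217 higher and 159 lower, and on log2(FPKM + 0.1) it gave 326 higher and 161 lower. The balance of rises and falls thus differed from that of edgeR, with the test, the genes tested and the scaling all changed together.

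Ugt1a2, which conjugates small molecules with glucuronic acid, rose most, from 12.5 ± 11.7 CPM in WT to 885 ± 1002 in KO (log2 fold change 6.13 ± 0.80, adjusted p = 0.00111). The KO mean of Ugt1a2 rested on the female KO replicate 3, with 2041 CPM against 267 and 348 in the KO males, which still lay above the WT libraries at 4.996 to 25.9. Ugt1a1 (2.69 ± 0.41) and Ugt1a10 (2.59 ± 0.49) rose too, as did the glutathione transferases Gsta1 (4.05 ± 0.99), Gsta5 (2.56 ± 0.38) and, from the oxidative stress list, Gsta2 (1.51 ± 0.25). The members of each of these families share much of their sequence, so the split of reads among them is uncertain. Gclc went the other way and fell, with 256 to 355 CPM in the KO libraries against 507 to 591 in WT. Pappa2, a protease of binding proteins of insulin-like growth factor, rose by 3.58 ± 0.65, the prolactin receptor Prlr by 2.82 ± 0.56, the kynurenine pathway enzyme Kynu by 2.69 ± 0.44, and Ltbp2, which binds elastic microfibrils, by 4.13 ± 0.93. In Ltbp2 the KO mean of 2.69 CPM rested on KO replicate 2, with 6.76 CPM against 0.620 and 0.693 in the other 2. The call of Ltbp2 was lost without KO replicate 2 and without any 1 WT library. Abcc3, Lpo and Atp13a4 completed the rises of the rule at 3.14 ± 0.71, 2.97 ± 0.78 and 2.46 ± 0.47. Abcc3 stood at 124 CPM in the female KO replicate 3, at 8.34 and 13.8 in the KO males and at 4.06 to 6.82 in WT. Its call was lost without KO replicate 3, without any 1 WT library and with sex as a covariate. Lpo stood at 3.26 CPM in KO replicate 2 and at 1.10 and 0.970 in the other KO libraries. The calls of Lpo and Gsta1 were also lost without KO replicate 2 or 3, without any 1 WT library and with sex as a covariate.

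The 12 largest falls included Slco1a1, Cyp7b1, Acsm3 and Cyp4a12a of the male-biased list. The organic anion transporter Slco1a1 had a log2 fold change of -6.08 ± 0.62 (342 ± 195 CPM in WT and 5.04 ± 3.93 in KO, adjusted p = 0.000317). The oxysterol hydroxylase Cyp7b1 fell from 127 ± 42.1 to 9.29 ± 5.27 CPM (-3.79 ± 0.34, adjusted p = 3.07e-05). The carboxylesterase Ces2b fell from 27.9 ± 15.2 to 2.30 ± 0.683, and the medium-chain acyl-CoA synthetase Acsm3 from 1384 ± 451 to 147 ± 130. Cyp4a12a fell from 34.3 ± 23.3 to 2.49 ± 0.932 CPM, and like Ces2b it has near-identical paralogs. The collagen chain gene Col6a6 fell from 39.8 ± 18.1 to 4.43 ± 3.91 CPM, the BMP antagonist Chrdl1 from 11.8 ± 3.70 to 1.40 ± 1.34, and the anion transporter Slc22a26 from 40.1 ± 6.08 to 5.17 ± 5.13. Sec14l3, Kcng1, Tmprss9 and Frmpd3 were the other large falls, at -3.63 ± 0.79, -3.44 ± 0.69, -3.08 ± 0.59 and -2.96 ± 0.42. The calls of Kcng1, Acsm3, Col6a6 and Slc22a26 were lost without KO replicate 2, and also without WT replicate 2 or WT replicate 3. That of Tmprss9 was lost without KO replicate 3 or WT replicate 2. Sec14l3 lost its call with DESeq2, with the replicate number as a block, without KO replicate 1 and without any 1 WT library. Slco1a1, Cyp7b1, Cyp4a12a, Ces2b, Chrdl1 and Frmpd3 kept theirs in each fit without 1 library. Lipoprotein lipase, Lpl, fell from 1339 ± 387 to 260 ± 82.4 CPM (-2.36 ± 0.26, adjusted p = 0.000317).

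Among 30 genes of the interstitial and fibrillar matrix, all 30 had a positive fold change at 4 weeks, with a median of 0.93. Over all genes 7 rose and 23 were not called, and adjusted over the list alone 19 rose. Elastin, Eln, was the firmest, at 17.9 ± 1.01 CPM in WT and 65.3 ± 12.3 in KO (1.87 ± 0.16, adjusted p = 2.28e-05). Mfap4 rose by 1.93 ± 0.34, fibulin 2 (Fbln2) by 1.12 ± 0.20 and the collagen-binding Sparc by 0.83 ± 0.16. The list passed camera with the preset correlation (adjusted p = 2.54e-11), but not with an estimated one (adjusted p = 0.402 with an estimated correlation) or fry (adjusted p = 0.0727). The list mean in KO replicate 1 was 4.02 on the log2 CPM scale, within the WT range of 3.89 to 4.29. KO replicates 2 and 3 stood at 5.55 and 4.98. Of 29 matrix proteases and inhibitors 5 rose, among them Mmp14 (1.16 ± 0.22) and the procollagen peptidase Adamts2 (1.66 ± 0.38). The inhibitor Timp3 fell from 2468 ± 259 to 1483 ± 210 CPM. Adjusted over the list alone 10 rose and 4 fell, and the list was not called (adjusted p = 0.0772). Of 30 basement membrane genes 0 rose and 1 fell, Fras1, at -0.71 ± 0.13, over all genes and adjusted over the list alone. The list was not called (adjusted p = 0.511).

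Of 25 podocyte markers at 4 weeks 5 rose, 0 fell and 20 were not called, with a median log2 fold change of 0.42, and 11 rose adjusted over the list alone. Nphs1, which encodes nephrin of the slit diaphragm, rose from 41.6 ± 5.75 to 69.3 ± 2.80 CPM. Ptpro rose by 0.90 ± 0.14 and Sema3g by 1.02 ± 0.17. The podocyte list passed camera with the preset correlation (adjusted p = 7.29e-08) and fry (adjusted p = 0.00402), with adjusted p = 0.246 with an estimated correlation. Its mean in each KO library (5.70, 5.73 and 5.92) lay above that in each WT library (5.30 to 5.39). Of 20 mesangial markers 4 rose, among them Rgs5 (0.94 ± 0.19) and Mcam (0.68 ± 0.14), both also markers of other pericytes. In that list 5 rose and 1 fell adjusted over the list alone (median 0.24, adjusted p = 0.00389, and adjusted p = 0.402 with an estimated correlation). The mesangial mean of KO replicate 1 was 3.93, within the WT range of 3.87 to 4.13, and only KO replicates 2 and 3 lay above it, at 4.35 and 4.31. Of 12 smooth muscle and renin cell markers 2 rose, with Tagln at 1.36 ± 0.29. In that list 7 rose adjusted over the list alone (median 0.77, adjusted p = 0.000336, and adjusted p = 0.402 with an estimated correlation). Acta2, smooth muscle actin, stood at 44.2 ± 8.34 CPM in WT and 98.3 ± 33.8 in KO with an adjusted p of 0.0538. Of 18 endothelial markers 2 rose, Plat (0.56 ± 0.11) and Tspan7 (0.46 ± 0.11), and 2 rose and 1 fell adjusted over the list alone. The list was not called (adjusted p = 0.0596).

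**Figure D3:**
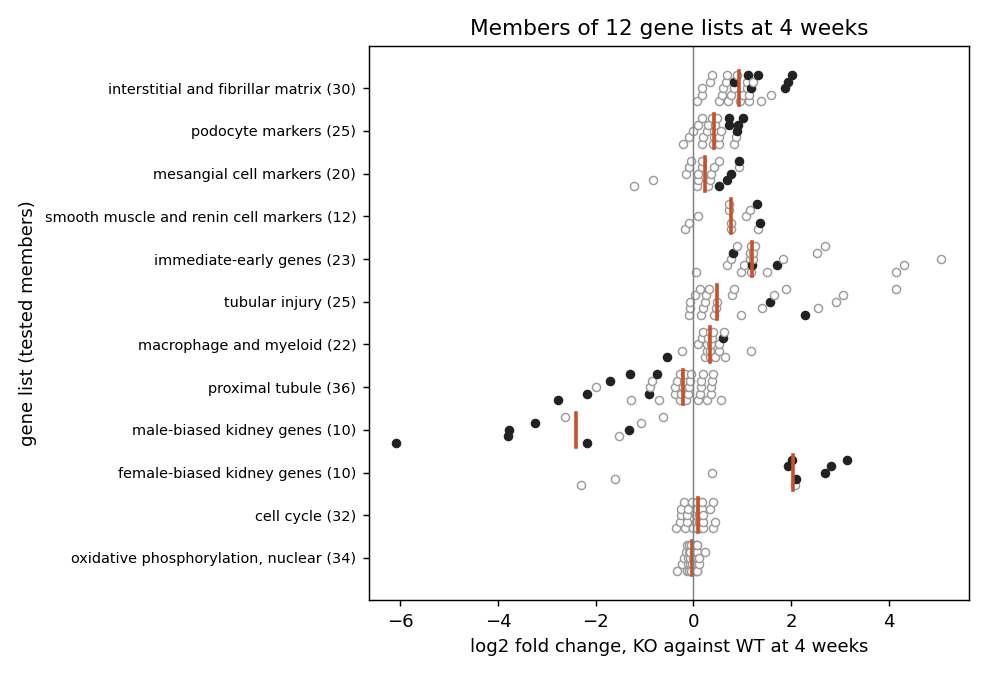
Log2 fold change of KO against WT at 4 weeks (horizontal axis) for each tested member of 12 gene lists (vertical axis, members tested in brackets). Filled points were called by edgeR and open ones were not, and the red bar is the median of the list. All 30 fibrillar matrix genes lie above 0 (median 0.93) and all 10 male-biased genes below 0 (median -2.41).

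Genes with a known male bias in mouse kidney were lower in KO at 4 weeks. Of 10 such genes 6 fell and 4 were not called, and 9 fell adjusted over the list alone, with a median of -2.41. Besides Slco1a1, Cyp7b1 and Acsm3, Hsd17b11 fell from 410 ± 108 to 164 ± 32.5 CPM. Of 10 genes listed as female-biased 6 rose, 0 fell and 4 were not called, with a median of 2.04. In that list 7 rose and 2 fell adjusted over the list alone. Among them were Prlr, Abcc3, Kynu, Gsta4 (2.09 ± 0.41) and Cyp4a14 (2.02 ± 0.50). Both lists passed camera with the preset correlation (adjusted p = 2.51e-12 and 0.000336) and fry (adjusted p = 0.00379 and 0.00673), with adjusted p = 0.246 and 0.281 with an estimated correlation. The female KO replicate 3 had the lowest level of all 10 male-biased genes among the KO libraries. The male KO replicates 1 and 2 also lay below every WT library of 4 weeks in 9 of the 10, and in all 9 they lay above every WT library of 2 weeks. The WT males of 4 weeks varied among themselves. The male-biased list mean was 7.50 log2 CPM in WT replicate 1, 8.41 and 8.29 in WT replicates 2 and 3, and 5.98 and 5.92 in the KO males. The female-biased mean was 5.80 in WT replicate 1, 4.69 and 4.77 in WT replicates 2 and 3, and 6.18 and 6.06 in the KO males. Of the 10 genes listed as female-biased, both KO males lay above every WT library of 4 weeks in 5 and below every one in 2, and the female had the highest level among the KO libraries in 7. The 2 genes were Rnf24 and Cyp2a4, which were lowest in the female among the KO libraries, at 3.29 and -0.199 log2 CPM. In these libraries they did not follow the bias of their list.

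Of 36 proximal tubule genes 6 fell and 30 were not called, with a median of -0.21. In that list 9 fell and 1 rose adjusted over the list alone (adjusted p = 0.000946, and adjusted p = 0.543 with an estimated correlation). The androgen-regulated Kap fell from 17661 ± 1629 to 7152 ± 2060 CPM and the organic anion transporter Slc22a7 from 276 ± 64.2 to 40.7 ± 35.1. The urate transporter Slc22a12 fell from 1740 ± 237 to 930 ± 267, and the brush border peptidase Ggt1 from 1310 ± 93.7 to 777 ± 130. Of 21 collecting duct markers 0 were called over all genes or adjusted over the list alone (median 0.38, adjusted p = 0.0248, and adjusted p = 0.402 with an estimated correlation). The call was lost without WT replicate 2 (adjusted p = 0.114) or KO replicate 3 (0.0676). Of 18 markers of the loop of Henle and distal convoluted tubule 2 rose, Nos1 (1.81 ± 0.43) and Cldn16 (0.53 ± 0.14), 3 adjusted over the list alone, and the list was not called (adjusted p = 0.129). Cldn16 lost its call in each fit without 1 library, Nos1 in each but that without KO replicate 1, and both with sex as a covariate. The 13 genes of the mitochondrial genome had a median of -0.27 with 0 called over all genes or adjusted over the list alone (adjusted p = 0.0333, and adjusted p = 0.753 with an estimated correlation). That call was lost without WT replicate 2 (adjusted p = 0.0569), WT replicate 3 (0.105), KO replicate 2 (0.181) or KO replicate 3 (0.118). For 32 cell cycle genes 0 were called by edgeR over all genes or adjusted over the list alone (median 0.09, adjusted p = 0.707).

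Immediate-early genes, which respond within minutes to stimuli and to tissue handling, had all 23 members at a positive fold change at 4 weeks, with a median of 1.201. Over all genes 3 rose, among them Ier3 (1.71 ± 0.35) and Klf4 (22.8 ± 11.5 CPM in KO). In that list 16 rose adjusted over the list alone (adjusted p = 1.28e-07, and adjusted p = 0.402 with an estimated correlation). The list mean was 2.52 in KO replicate 1, within the WT range of 2.31 to 2.72, and 3.70 and 4.87 in KO replicates 2 and 3. Of 25 tubular injury genes 2 rose, Spp1 (2.29 ± 0.30) and Vcam1 (1.57 ± 0.33). In that list 6 rose adjusted over the list alone (median 0.49, adjusted p = 0.000336, and adjusted p = 0.402 with an estimated correlation). KO replicate 2 held the highest level of 19 of the 25 among the libraries of 4 weeks. There Havcr1, which encodes the injury marker KIM-1, stood at 50.2 CPM against at most 1.31 in any other library, and without KO replicate 2 the list was not called (adjusted p = 0.169). Spp1 was above every WT library in all 3 KO libraries, at 2389, 6835 and 7062 CPM against 983 to 1339. Of 22 macrophage and myeloid markers H2-Ab1 rose (0.61 ± 0.15), Csf1r fell (-0.54 ± 0.11) and 20 were not called. In that list 3 rose and 1 fell adjusted over the list alone (median 0.34, adjusted p = 0.00126, and adjusted p = 0.402 with an estimated correlation). KO replicate 2 held the highest level of 16 of the 22 at 4 weeks, and without it the list was not called (adjusted p = 0.0752). Of 19 integrins Itga11 rose (2.12 ± 0.50), 2 adjusted over the list alone (median 0.22, adjusted p = 0.0166, and adjusted p = 0.402 with an estimated correlation), and the list call was lost without WT replicate 1 (adjusted p = 0.0845). Itga11 itself lay at 0.0665 to 0.796 CPM in the libraries of 4 weeks. Its call was lost with DESeq2, with sex as a covariate, without KO replicate 2 or 3 and without any 1 WT library. The mean of KO replicate 1 lay within the WT range for the injury, integrin, collecting duct and mitochondrial lists as well.

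**Figure D4:**
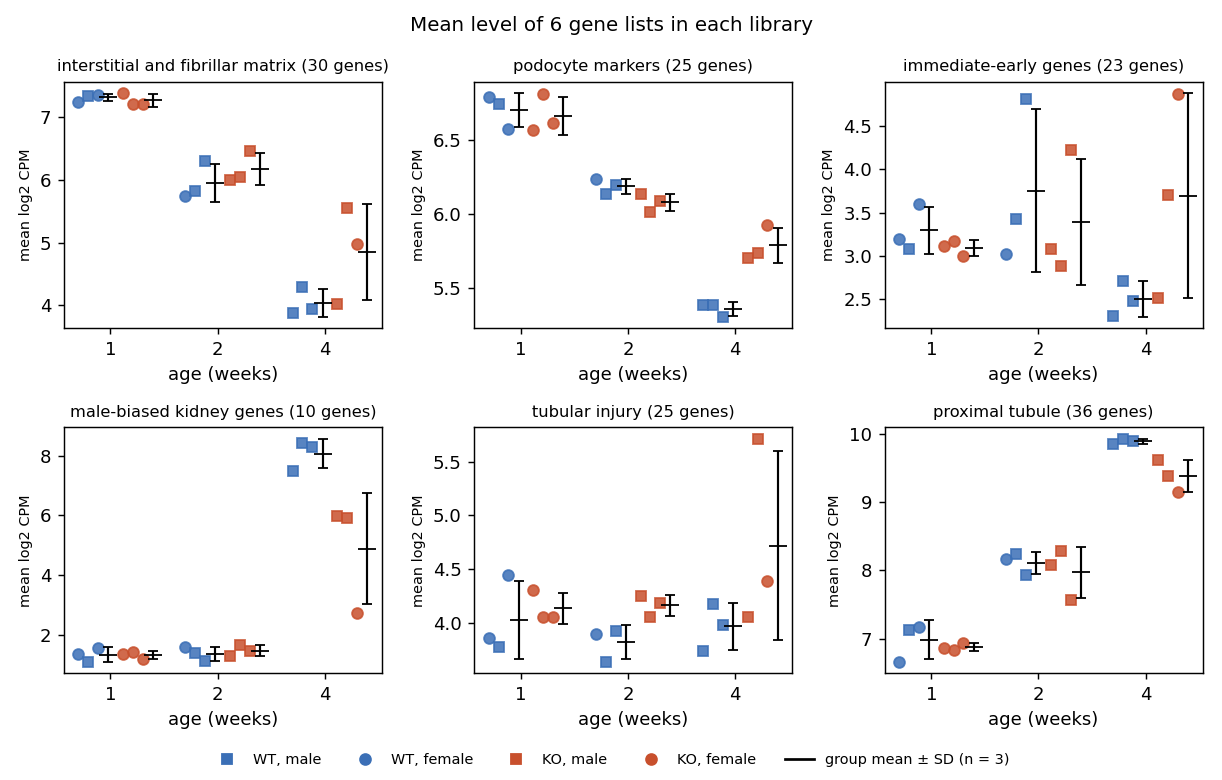
Mean log2 CPM of 6 gene lists (vertical axes) against age in weeks (horizontal axes), 1 point per library, WT in blue and KO in red, squares for males and circles for females, with the group mean and SD (n = 3) beside the points. At 4 weeks the podocyte mean lies between 5.70 and 5.92 in KO and between 5.30 and 5.39 in WT, while the matrix mean of KO replicate 1 (4.02) lies within the WT range.

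The extent of the 4-week difference depended on the libraries. Fitting the 6 libraries of that age alone called 2 genes, Ecm1 and Eln, with 2112 at an unadjusted p under 0.05. With sex as a covariate 266 genes were called, with DESeq2 937 and with the replicate number as a block 931. Leaving out 1 library gave 89 without WT replicate 2, 105 without WT replicate 3, 139 without the female KO replicate 3, 223 without KO replicate 2 and 1201 without KO replicate 1. Without both KO replicates 2 and 3, an alternative chosen after seeing the data, 18 genes were called. Of the 68 called genes among those singled out for the text, 22 kept their call in each of the 6 fits without 1 library and 52 kept it with sex as a covariate. Sex entered as an additive term shared by all ages, and KO replicate 3 was the only female of 4 weeks. The covariate therefore cannot remove a sex difference that is present at 4 weeks only. The 22 included Eln, Mfap4, Ptpro, Sema3g, Spp1, Slco1a1, Cyp7b1, Hsd17b11, Lpl, Kynu and Ugt1a2, and did not include Nphs1, Kap, Prlr or Acsm3. Camera called 13 lists at 4 weeks with the preset correlation, 22 without KO replicate 1, 0 with an estimated correlation and 4 by fry.

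Averaged over the 3 ages, 5 genes were called between KO and WT, with 1335 at an unadjusted p under 0.05. Eln (0.76 ± 0.09, adjusted p = 0.00135) and Mfap4 (1.04 ± 0.17, adjusted p = 0.0455) rose, and Ecm1 (-9.93 ± 0.26), the chromatin factor gene Asxl3 (-0.74 ± 0.10, adjusted p = 0.00979) and the filaggrin gene Flg (-2.48 ± 0.38, adjusted p = 0.0265) fell. Flg had group means under 1 CPM, and it lies on chromosome 3 from 93273523 to 93293686, near Ecm1. Mfap4 lost its call in 16 of 25 alternative settings and Flg in 13 of 22, the replicate number as a block among them. Eln and Ecm1 kept theirs in all 25, and Asxl3 lost its own only on the 2 FPKM scales. Cyp7b1 missed the threshold (-1.13 ± 0.19, adjusted p = 0.0518). The count was 104 with DESeq2, 19 with the replicate number as a block, 29 without WT replicate 1 of 4 weeks and 82 without KO replicate 1 of 4 weeks, and it was 3 with the stricter expression filter. It was also 3 without any 1 of WT replicates 1 and 2 and KO replicates 1, 2 and 3 of 1 week, WT replicates 2 and 3 and KO replicate 2 of 2 weeks, and WT replicate 2 of 4 weeks, and in each of these 9 fits the calls lost were those of Mfap4 and Flg.

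The genotype difference itself changed with age for 21 genes by the interaction test, with 1062 at an unadjusted p under 0.05. Cyp7b1 had log2 fold changes of 0.29, 0.10 and -3.79 at 1, 2 and 4 weeks (adjusted p = 0.00248). Eln had 0.17, 0.26 and 1.87 (adjusted p = 0.00601), and Ugt1a2 0.13, -0.85 and 6.13 (adjusted p = 0.0187). The dipeptidase gene Cndp2 went from 0.09 and -0.03 to -1.71, Lpl from -0.01 and -0.14 to -2.36, and Asxl3 from -0.24 and -0.09 to -1.89, each with an adjusted p of 0.0187. With the replicate number as a block Cndp2, Lpl and Ugt1a2 were no longer called, and of these 6 genes only Cyp7b1 kept its call in all 25 alternative settings. Of the pairwise differences, 26 genes were called between 4 and 2 weeks, 9 between 4 and 1 week, and 0 between 2 weeks and 1 week by edgeR, where 127 had an unadjusted p under 0.05. The 21 genes became 185 with DESeq2, 11 with the replicate number as a block, 1 without WT replicate 2 of 4 weeks and 192 without KO replicate 1 of 4 weeks, and it was 55, 4, 5 and 5 without WT replicate 1, WT replicate 3, KO replicate 2 and KO replicate 3 of 4 weeks. Without any 1 library of 1 or 2 weeks, in either genotype and for each replicate number, the count fell to between 5 and 12.

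In WT kidneys transcripts of the proximal tubule and of oxidative phosphorylation rose with age, and those of the fibrillar matrix, podocytes and the cell cycle fell. From 1 to 2 weeks 3481 genes were called (1842 up, 1639 down), and from 2 to 4 weeks 7138 (3468 up, 3670 down). Of 36 proximal tubule genes 26 rose in the first step and 27 in the second, and of 34 nuclear oxidative phosphorylation genes 31 rose in each. Of 30 fibrillar matrix genes 23 and 25 fell, of 25 podocyte markers 12 and 20 fell, and of 32 cell cycle genes 8 and 28 fell. Adjusted over the list alone, 28 and 29 proximal tubule genes and 32 and 31 oxidative phosphorylation genes rose, and 25 and 26 matrix genes, 14 and 20 podocyte markers and 11 and 28 cell cycle genes fell. All 10 male-biased genes rose from 2 to 4 weeks, where only 1 had risen before, with Slco1a1 going from 0.0197 ± 0.0342 to 342 ± 195 CPM. These lists passed camera with the preset correlation in both steps (adjusted p at most 1.53e-05 from 2 to 4 weeks) except the male-biased list in the first, and none did with an estimated correlation (adjusted p at least 0.2509 and 0.2204 with an estimated correlation in the 2 steps).

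Among the single genes of the first step in WT, the peroxisomal acyltransferase gene Acnat2 rose from 1.32 ± 0.408 to 28.1 ± 6.29 CPM and the hyaluronan synthase Has2 fell from 3.14 ± 0.649 to 0.0336 ± 0.0304. The protease Adamts19 fell from 5.24 ± 1.07 to 0.109 ± 0.104. Chga, of chromaffin cells, and Serpinc1, of hepatocytes, also fell, from 24.2 ± 40.5 to 0.103 ± 0.0899 CPM and from 4.39 ± 6.83 to 0.0909 ± 0.0950, but WT replicate 3 of 1 week alone held 70.9 and 12.3 CPM. Zbtb16, a transcription factor gene induced by glucocorticoids, rose from 0.385 ± 0.141 to 21.3 ± 30.8 CPM, with 56.8 CPM in WT replicate 1 of 2 weeks. In the second step Serpina6, which encodes the cortisol-binding globulin, fell from 3459 ± 880 to 6.78 ± 9.06 CPM. The retinol dehydrogenase Rdh19 fell from 96.3 ± 9.53 to 0.201 ± 0.177, and Adamts17 fell from 22.8 ± 5.45 to 0.113 ± 0.142. Cyp2a4 rose from 0.0513 ± 0.0479 to 87.0 ± 36.4 CPM, Akr1c18 from 0 in all 3 libraries to 34.3 ± 2.59, and Nat8f6, whose paralogs share its reads, from 0.0197 ± 0.0342 to 162 ± 20.9. Without WT replicate 1 of 1 week the first step called 2291 genes.

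In KO kidneys 2881 genes were called from 1 to 2 weeks (1527 up, 1354 down) and 5447 from 2 to 4 weeks (2690 up, 2757 down). In the first step 1285 genes rose in both genotypes and 1116 fell in both, where independent lists of these sizes would share 190 and 150, and none went opposite ways. In the second step 2293 rose and 2333 fell in both, against 631 and 685 for independent lists, and 2 and 10 genes, by the direction in WT, were called in opposite directions. Has2 fell in KO from 3.31 ± 1.06 to 0.0631 ± 0.109 CPM and Adamts19 from 5.55 ± 0.595 to 0.0655 ± 0.0717 in the first step. Adamts17 fell from 33.7 ± 11.5 to 0.271 ± 0.130 and the cadherin gene Fat3 from 11.9 ± 4.79 to 0.126 ± 0.0979 in the second. The Y-linked genes Ddx3y and Uty went from 0 to 61.9 ± 24.8 and 25.2 ± 2.37 CPM in the first step, since the 3 KO mice were female at 1 week and male at 2 weeks. Without KO replicate 2 of 1 week the first step called 1701 genes, and without KO replicate 2 of 2 weeks 1702.

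The balance of rises and falls with age differed between edgeR and limma on FPKM, which change the test, the genes tested and the scaling together. On log2(FPKM + 1), which applies no scaling between libraries beyond the total, the median gene shifted by -0.18 from 1 to 2 weeks and by -0.40 from 2 to 4 weeks in WT. By this test 836 genes rose and 3170 fell in the first step and 1193 rose and 7006 fell in the second. In KO the shifts were -0.17 and -0.31, with 748 up and 2795 down and then 989 up and 5877 down. On log2(FPKM + 0.1) the WT splits were 827 up and 2853 down and then 1181 up and 7135 down, and the KO splits 725 up and 2413 down and then 984 up and 5978 down. The lists named for the steps in age kept the sign of their median on each scale, apart from the male-biased list from 1 to 2 weeks, which was not called.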

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

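The explanations weighed in this part were written after the results had been seen, while the other groupings of the libraries were planned before the data were examined, apart from the one that leaves out Ecm1 and the restriction to splits that part the pairs. What drew attention here was that the difference between KO and WT was not the same at the 3 ages, by the edgeR interaction test. It passed for 21 genes, led by Cyp7b1 (adjusted p = 0.002476) and Eln (adjusted p = 0.006006). Asxl3, Cndp2, Ugt1a2 and Lpl followed, each with an adjusted p of 0.01869. Libraries were also regrouped within each age, over 100 splits, the real one among them. As many as 21 interaction genes came in 6 of the 100, and the highest other split gave 181, so a random grouping of the libraries could give that count. Those splits ignore the pairing at 2 weeks. Among the 37 that part every pair of 2 weeks, as the real one does, 2 gave as many (highest other 33), which also leaves a random grouping open, and with the replicate number as a block 11 genes were called, 6 of them among the 21 and none of these Cndp2, Ugt1a2 or Lpl.

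Many genes differed between KO and WT at 4 weeks (477), and 3 explanations were tried. If the female KO mouse were the whole cause, few genes would remain without it, and 139 were called. If the injured kidney, KO replicate 2, were the whole cause, few would remain without that library, and 223 were called. Each of these fits kept the other library, so the 2 libraries together are not excluded as the cause. Without both a single KO library is left, so the spread of KO at this age cannot be measured. A fit without the 2 libraries therefore cannot settle the point. The hypothesis of slower postnatal maturation predicts KO kidneys nearer to younger ones, and an index of the genes that changed in both genotypes from 1 to 2 weeks (1285 up, 1116 down) was 0.356 lower in KO (4.35 ± 0.177, n = 3) than in WT (4.71 ± 0.0404, n = 3). All 3 KO libraries lay below every WT library, with an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow. KO replicate 1 stood at 4.55, just below the WT libraries at 4.66 to 4.73, and KO replicates 2 and 3 at 4.22 and 4.28. The KO share of the WT change from 2 to 4 weeks was uneven across the lists named for the steps in age. It was 97.0 ± 41.1% for cell cycle, 93.9 ± 34.5% for oxidative phosphorylation and 71.4 ± 13.1% for proximal tubule genes. For matrix, male-biased and podocyte genes it was 57.7 ± 40.2%, 52.5 ± 27.7% and 48.4 ± 14.5%. Slower maturation remains possible but is not shown.

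Male-biased genes were lower in KO at 4 weeks, which the female KO mouse could produce, but without it the list passed camera with an adjusted p of 1.13e-15 at the preset correlation, and both KO males lay below every WT library in 9 of the 10 genes. With all libraries the list had an adjusted p = 0.246 with an estimated correlation. An even loss of proximal tubule cells, as the only cause, would lower all tubule genes alike. The proximal tubule median, however, lay 2.20 above the male-biased median on the log2 scale. A loss that is uneven along the tubule, or that acts with another cause, is not excluded by these medians. A later onset of the male pattern predicts KO males between WT kidneys of 2 weeks and of 4 weeks, and 9 of 10 genes lay there in both KO males. Any partial lowering would also lie there, since the 2 WT ages were far apart in these genes. Slco1a1 was at most -2.57 log2 CPM in WT at 2 weeks with a mean of 8.20 at 4 weeks, and Acsm3 1.36 and 10.4. The result therefore does not favour a later onset over another cause of lower levels. The 3 WT males differed among themselves in these genes, and there were only 2 KO males. With no measure of puberty in the sources used here, a later onset is not shown. If there was one, it may have nothing to do with Ecm1.

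Within 20 Mb of Ecm1, 11 of 351 genes (3.13%) had an unadjusted p under 0.001 in the average over ages, where 1.62 would be expected. Among the 11, Tmem144, Glrb, Rbm46 and Vav3 lay at -15.9, -14.9, -12.9 and 13.6 Mb from Ecm1. Of 67 other windows of 40 Mb, 0 had as high a share. The highest of them, at 2.50%, also lay on chromosome 3, in the window starting at 120000001, and the next, at 1.82%, on chromosome 1. Alleles of another strain carried along with the targeted locus predict such a cluster, and Flg, Acp6 and Selenbp2 were among the 11 genes. A list of neighbours of Ecm1 fixed beforehand (22 tested) does not add to this, with medians of -0.01, 0.02 and 0.05 at 1, 2 and 4 weeks and no call by camera (smallest adjusted p = 0.0949, at 4 weeks), and a list of mouse strain variants was called at 2 weeks alone (adjusted p = 0.0199, and adjusted p = 0.313 with an estimated correlation) and in only 2 of 6 fits without 1 library. For a chance position of a few genes, Fisher's exact p, which takes genes as independent, was 5.39e-07 for the 11 genes. It was at most 0.0265 at each of the 3 ages for genes with p under 0.01. For p under 0.001 it was 0.135 at 2 weeks, where only 6 genes passed and 1 of them lay near Ecm1. The window and the thresholds were set after the cluster was seen in these same libraries, so these tests cannot exclude a chance position. The strain is not given in the sources used here, and an effect of the deletion on neighbouring genes could give the same cluster, which the data cannot separate.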

How the results depend on the processing

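The absence of Ecm1 from KO kidneys held in every setting. Of 116 calls of single genes, 34 held in every setting, 82 were lost in at least 1, and 0 turned round. The 116 include the steps in age, which were not fitted with sex as a covariate or within 1 age. Of the 68 calls between KO and WT at 4 weeks, only those of Ecm1 and Eln held in every setting. For KO against WT at 1 week the count of 1 became 4 with DESeq2 and 2 with limma on log2(FPKM + 1) or log2(FPKM + 0.1), and at 2 weeks 1 became 2 with DESeq2. At 4 weeks 477 became 937 with DESeq2, 2 with only the 6 libraries of that age, 266 with sex as a covariate, 200 with a minimum log2 fold change of 1, and 18 without KO replicates 2 and 3, an alternative chosen after seeing the data. Fewer libraries and degrees of freedom lower such counts by themselves. The sex covariate was shared by all ages, so it cannot remove a sex difference that is present at 4 weeks only. For the average over ages 5 became 104 with DESeq2 and 3 with the filter of 1 CPM in 3 libraries, and for the interaction 21 became 185 with DESeq2. Leaving out 1 library gave 89 to 1201 genes at 4 weeks, 3 to 82 for the average, 1 to 192 for the interaction, 2291 to 3451 for WT and 1701 to 2994 for KO from 1 to 2 weeks. The called lists, 7, 13 and 13 at the 3 ages, became 0, 0 and 0 with an estimated correlation and 0, 0 and 4 by fry, and 3 to 12, 7 to 17 and 12 to 22 without 1 library. For the other changes the cause was not tested. Every alternative set down before the data were examined was run.

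With the replicate number as a block 931 genes were called at 4 weeks, 19 for the average and 11 for the interaction. The numbers were taken to pair the libraries at 2 weeks only, so the block has no ground of its own at 4 weeks. It was fitted over all 18 libraries in 1 model, however, and so also took the replicate spread of 2 weeks out of the spread shared by all ages. The main model leaves that spread in. With the block the genes at an unadjusted edgeR p under 0.05 went from 196 to 428 at 1 week, from 249 to 534 at 2 weeks and from 2526 to 3367 at 4 weeks. The cause of the changed counts was not tested. Depth, at 14930565 to 21427764 counts per library, limits the low genes such as Flg, with group means under 1 CPM.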

Other observations

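Some libraries carried genes of other tissues or of a state of the tissue. In WT replicate 3 of 1 week the adrenal gene Star, which moves cholesterol into mitochondria for steroid synthesis, stood at 98.2 CPM against at most 6.27 in the other 17 libraries, and the chromaffin gene Chga at 70.9 against at most 2.41. The same library held 458 CPM of albumin (Alb) against at most 6.27 in the others of 1 week, and the highest level of 12 of 18 hepatocyte markers in a list added after the data were seen. Immediate-early genes stood highest in KO replicate 3 of 4 weeks (Fos 40.3 CPM, Egr1 128, Nr4a1 121) and in WT replicate 3 of 2 weeks (Fos 23.4, Egr1 100, Nr4a1 122). In KO replicate 2 of 4 weeks the injury genes Havcr1 and Lcn2 stood at 50.2 and 97.0 CPM against at most 1.31 and 18.04 elsewhere. Alb, Egr1 and Lcn2 were chosen after their values were seen.

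At 2 weeks both replicates 1 stood apart from the other 4 libraries in genes chosen after their values were seen. The oxidative stress regulator Nfe2l2 had 42.1 CPM in WT and 43.6 in KO replicate 1 against 154 to 172 in the others, Cpne1 had 6.75 and 8.18 against 39.8 to 53.0, and Svil had 36.2 and 35.4 against 81.2 to 91.7. The edgeR adjusted p for the replicate number was 4.08e-05, 8.14e-05 and 8.74e-05 for Cpne1, Nfe2l2 and Svil. Serpina6, high in all libraries of 2 weeks, stood at 1856 CPM in the female KO mouse of 4 weeks and at 0.637 to 17.2 in the 5 males. Ugt1a2 stood at 2041 CPM in that female and at 267 and 348 in the KO males, against 4.996 to 25.9 in the WT males of 4 weeks.

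The other groupings in this part were planned before the data were examined, except the one without Ecm1 and the restriction to splits that part the pairs, which were chosen after the result was seen. With 10 splits of 6 libraries, the splits are too few for a share under 0.05. Counts as large as the real one came in 1 of 10 splits for KO against WT at 1 week (1, highest other 0), in 2 at 2 weeks (1, highest other 896) and in 1 at 4 weeks (477, highest other 16). For the steps in age it was 1 of 10 each, with 3481 and a highest other of 1 and 7138 and 0 in WT, and 2881 and 0 and 5447 and 2 in KO. For the lists it was 10 of 10 at 1 week (7, highest other 15), 4 at 2 weeks (13, highest other 19) and 4 at 4 weeks (13, highest other 21). The split with 896 genes set KO replicates 1 and 2 and WT replicate 1 of 2 weeks against the rest, and among the 4 splits that part every pair the highest other was 0 genes and 10 lists. Over 100 splits within ages the average over ages reached 5 genes in 2 (highest other 14), so a random grouping of the libraries seldom gave as many, but without Ecm1 it reached 4 in 7 of 100 (highest other 14), which a random grouping could give. Among the 37 of these splits that part every pair of 2 weeks, only the real one reached 5 genes, or 4 without Ecm1, and the highest other gave 2 in both counts.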
